A study of Mus musculus with 21 samples.

How the data were processed

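The series covers bulk RNA sequencing of microglia sorted by flow cytometry from the striatum of male mice 8 to 10 weeks old. Sorted cells were live, CD11b positive, CD45 low and P2RY12 positive, per the labels' protocols, from offspring of control dams or of dams with maternal immune activation (MIA). They were collected 18 hours after an intraperitoneal injection of saline or of lipopolysaccharide (LPS) at 4500 endotoxin units per gram. Libraries were made from 5 ng of RNA with a modified Smart-Seq2 protocol, which primes reverse transcription at the poly(A) tail, and 9 PCR cycles, per the labels' protocols. The reads carry no molecular identifiers as far as the protocol says, so counting floors cover counting error only.

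The deposited table held estimated counts per gene, not normalized, for 55487 genes in 21 libraries. RSEM, STAR and DESeq2 are named in the submitters' processing notes, without versions or roles, and the genome build and annotation are not given in the sources used here. Of the values, 73018 (6.27%) were not whole, as estimated counts can be, and all were rounded before any count test. The table gives versioned Ensembl identifiers without symbols. Symbols and coordinates came from the GENCODE M21 annotation of GRCm38, which held 55141 of the identifiers when the version was left off and 54435 with it, and 346 had no match. Whether reads were counted by strand and how reads of gene copies were shared are not given in the sources used here, so genes of families with close copies and antisense genes are uncertain. No count was seen in any library for 28208 genes.

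Groups came from the labels: control saline (6 libraries), control LPS (5), MIA saline (6) and MIA LPS (4). MIA saline replicate 6 was titled excluded by the submitters and stayed out of the fit. Batch 2 held a single library, MIA LPS replicate 4, so the batch term took up that library and each contrast compared 6, 5, 5 and 3 libraries of batch 1. Total counts of the fitted batch 1 libraries (M, counts in units of 1e+06) were 11.9 to 19.0 M (control saline), 9.85 to 18.1 M (control LPS), 10.2 to 15.7 M (MIA saline) and 13.0 to 17.1 M (MIA LPS). A group total of 3 counts, the floor used for genes with 0 counts in a group, equals 0.0333, 0.0416, 0.0440 and 0.0735 counts per 1e+06 counts (CPM) in these groups. Replicate pairs of a group differed by more than sampling noise in every case (chi-square over degrees of freedom at least 5.96, genes with a summed count of at least 20), so no library was counted as a copy of another.

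The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit, TMM scaling) with 1 mean per maternal group and treatment plus batch, on all 20 libraries in 1 fit with 15 residual degrees of freedom. Genes passed edgeR's expression filter at a minimum count of 10 and a minimum total of 15, which left 14741 genes with 99.9% of the counts. A call is a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.252. The standard error (SE) of a log2 fold change was back-calculated, as its absolute value over the square root of the test's F statistic. The median standard error of a log2 fold change was 0.22 (LPS in control), 0.27 (LPS in MIA), 0.34 (difference of responses), 0.22 (MIA against control after saline) and 0.26 (after LPS). Group means and SDs are TMM-scaled CPM over batch 1 libraries, and summed CPM of cell type lists are relative to a library's total count. The size of the response is the median, over genes with a called mean LPS effect of both maternal groups, of the signed MIA minus control difference, where a smaller response in MIA gives a negative value. Principal components were computed on log2 CPM with a prior count of 2.

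Gene lists, 15 for biology and 9 for cell types with 414 genes of which 376 were measured, the comparisons, the test, the alternatives named as planned and the rule for named genes were fixed before the data were examined. Lists were tested with limma's camera (limma 3.58.1) at a preset correlation between members of 0.01, adjusted over the lists of a kind. They were tested again with an estimated correlation and with fry. Lists of fewer than 3 measured genes were not tested. Biology lists were homeostatic microglia, cytokines and chemokines, interferon-stimulated genes, TLR and NF-kB signalling, antigen presentation, disease-associated microglia and lysosome, complement, phagocytic receptors and bridging factors, glycolysis, oxidative phosphorylation, ribosomal proteins, cell cycle, immediate early and dissociation stress, chromatin modifiers and glucocorticoid-responsive genes. Cell type lists were neuron, astrocyte, oligodendrocyte, endothelial and mural, border-associated macrophage, monocyte, neutrophil, lymphocyte, and erythroid and choroid plexus. Named genes were, per comparison, drawn from the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 3, leaving out Gm-numbered, Rik, mitochondrial and ribosomal protein genes. They were also drawn from the 3 largest called changes of each list, or the 2 highest-expressed members where none was called. The sort markers Itgam, Ptprc and P2ry12 were named in every comparison, and where fewer than 10 genes were called, the next by p were named up to 10 in all. Other named genes are said to be chosen after their values were seen. Values of 1 marker gene are not reported here.

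This fit was tested on counts simulated from the real genes' means and spread and the real library sizes, in which 100 genes were changed by 2-fold and 100 by 4-fold. Apart from these changes all groups shared a common mean per gene, without an LPS or batch effect. Changed genes were drawn only above a minimum mean expression. Genes were drawn independently, so structure shared by genes of a library was not simulated and recovery in the real libraries may be lower. Of 2-fold and 4-fold changes, 76% and 95% were recovered for LPS in control offspring, 68% and 95% for LPS in MIA offspring, 44% and 84% for the difference of responses, 79% and 97% after saline and 65% and 95% after LPS. A simulated MIA response at 75% of the control response gave a size of -0.24, and an equal response 0.02. Alternatives were the fit without a batch term, with the library titled excluded, with RLE or upper quartile scaling, with no filter or a mean CPM of at least 10, limma-voom with sample weights, DESeq2 1.42.0, a replicate block and the second number of the ID label as a random block. Further alternatives were a 2-fold minimum, the log2 number of detected genes as a covariate, only the 2 groups compared, and each library left out in turn. Fits without the ribosomal RNA gene CT010467.1, and the counts of called lists and the border macrophage and oligodendrocyte lists under each edgeR alternative, were added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.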

Results

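Polyadenylated RNA of microglia sorted from the striatum of male mice was measured by RNA sequencing in 21 libraries. The cells, the resident macrophages of the brain, were live, CD11b positive, CD45 low and P2RY12 positive. The mice were offspring of control dams or of dams with maternal immune activation (MIA), an immune challenge during pregnancy, and received lipopolysaccharide (LPS), a bacterial cell wall component, or saline 18 hours before collection. The LPS dose was 4500 endotoxin units per gram of body weight. The groups held 6 control saline, 5 control LPS, 6 MIA saline and 4 MIA LPS libraries. MIA saline replicate 6 is titled excluded by the submitters and was left out. MIA LPS replicate 4 alone came from batch 2, so every contrast rested on 19 batch 1 libraries. Their total counts ran from 9.85 M in control LPS replicate 3 to 19.0 M in control saline replicate 5. The batch 2 library held 11.4 M and the library titled excluded 5.29 M. The ribosomal RNA gene CT010467.1 took 47.95% of all counts on average, followed by mt-Rnr2 at 3.71% and Cst3 at 1.48%. Genes with a count numbered 17995 to 19559 in batch 1 libraries of the fit, 12264 in the batch 2 library and 16819 in the library titled excluded. The labels do not say which mice shared a litter, so p-values measure the spread between these samples. The second number of the ID label took only 3 values among the batch 1 MIA libraries of the fit and 6 among the control libraries. What this number marks is not stated. If it marks a litter or dam, the p-values treat related mice as independent.

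Treatment separated the batch 1 libraries. The first principal component held 56.4% of the variance of these 19 libraries and ran from -63.5 to -52.4 in the 11 saline libraries and from 69.8 to 91.3 in the 8 LPS libraries. The second held 6.86%, with MIA LPS replicate 2 at 83.4 and the other 18 libraries between -30.9 and 17.9. That library also had the highest summed counts per 1e+06 counts (CPM) of astrocyte markers among the LPS libraries, 235 against at most 146, and of oligodendrocyte markers, 89.7 against at most 44.8. The sort markers Itgam, which encodes CD11b, and Ptprc, which encodes CD45, were not called between LPS and saline in either maternal group. Itgam stood at -0.01 ± 0.14 (log2 fold change ± SE) in control offspring (edgeR adjusted p = 0.965) and at -0.04 ± 0.17 in MIA offspring (edgeR adjusted p = 0.883). For Ptprc the values were -0.24 ± 0.14 (edgeR adjusted p = 0.159) and -0.18 ± 0.17 (edgeR adjusted p = 0.415). Ptprc was called lower in control offspring without control LPS replicate 3 (-0.37) and by limma-voom with sample weights (-0.28), and in MIA offspring without MIA LPS replicate 2 (-0.48) and by limma-voom with sample weights (-0.40).

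**Figure D1:**
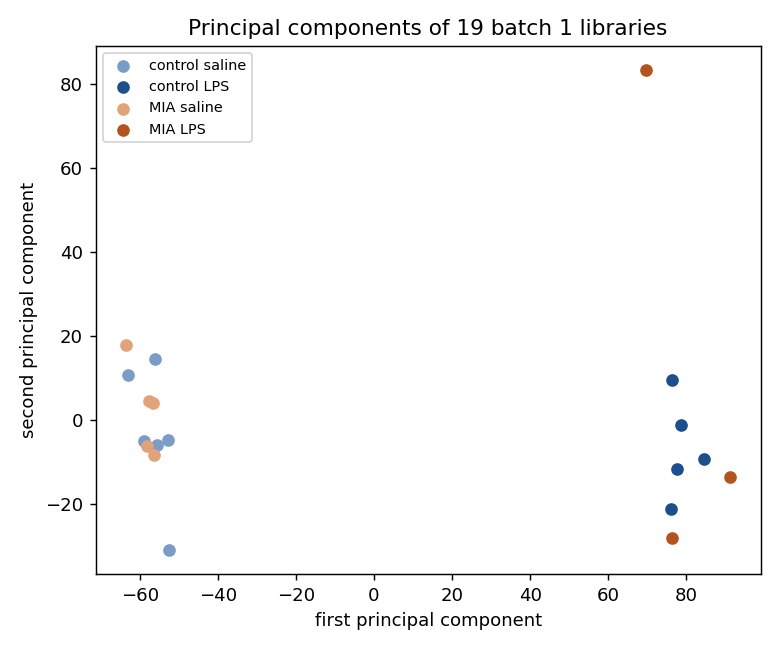
First and second principal components of the 19 batch 1 libraries, without units, with each point 1 library coloured by maternal group and treatment. Saline libraries lie between -63.5 and -52.4 on the first component and LPS libraries between 69.8 and 91.3, while MIA LPS replicate 2 stands at 83.4 on the second.

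The first comparison asked how adult LPS changed striatal microglia of control offspring (6 saline and 5 LPS libraries). Genes that mark resting microglia fell and cytokine and interferon-response genes rose. P2ry12, the purinergic receptor used in the sort, fell from 1974 ± 198 CPM (SD, n = 6) to 188 ± 17.3 (SD, n = 5). Il1r2, the decoy receptor of interleukin 1, rose from 0.122 ± 0.210 to 339 ± 60.9 CPM, and Lcn2, an iron-sequestering acute phase protein, from 1.14 ± 1.00 to 282 ± 112 CPM. Marco, a scavenger receptor, had 0 counts in all 6 saline libraries and 48.9 ± 13.5 CPM after LPS, at least 1470.1-fold higher against a floor of 3 counts over the saline group. Of 14741 genes tested, 6580 were called by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 3439 higher and 3141 lower after LPS. Which direction held more genes depended on the scaling, with 3019 and 3578 higher and lower under RLE, 2957 and 3654 under upper quartile scaling and 3122 and 3741 by DESeq2, and with the library titled excluded kept in they were 3317 and 3323. At least 2-fold changes were found in 1567 of the higher and 1665 of the lower genes.

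**Figure D2:**
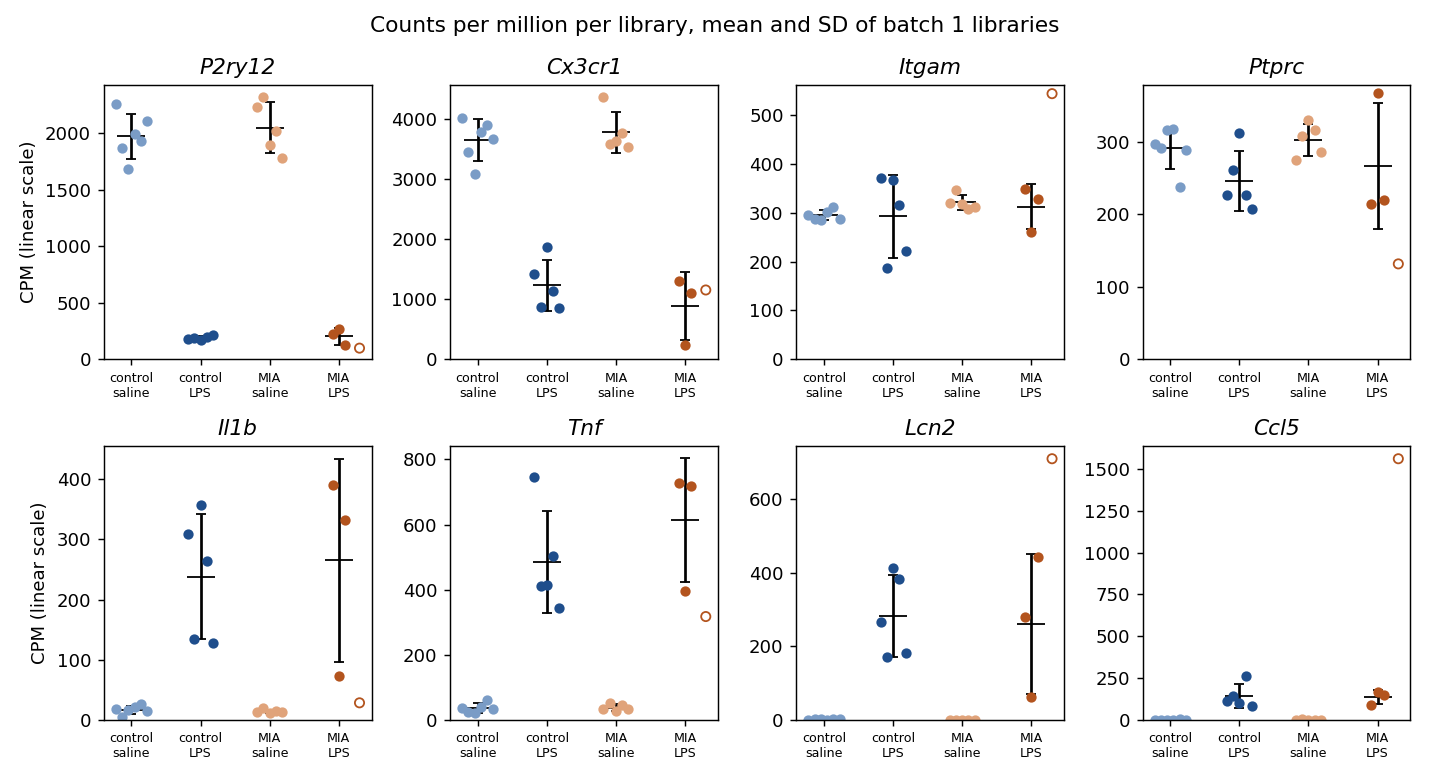
CPM on linear axes for 8 genes, with filled points for batch 1 libraries of each group, bars for mean and SD, and an open point for the batch 2 library. P2ry12 had means of 1974 and 188 CPM after saline and LPS in control and 2049.9 and 203 CPM in MIA offspring, Cx3cr1 was lower and Il1b, Tnf, Lcn2 and Ccl5 were higher after LPS in both, and Itgam and Ptprc were not called.

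The homeostatic list held 26 measured genes, of which 23 fell and 1 rose (1 and 24 adjusted over the list alone), with a median log2 fold change of -1.64 (camera adjusted p = 4.32e-24). The fructose transporter gene Slc2a5 changed by -5.75 ± 0.23 (log2 fold change ± SE, edgeR adjusted p = 7.89e-16), Crybb1 by -4.65 ± 0.29 (edgeR adjusted p = 3.98e-11) and the receptor gene Gpr34 by -4.20 ± 0.28 (edgeR adjusted p = 4.30e-11). P2ry12 changed by -3.39 ± 0.17 (edgeR adjusted p = 2.76e-14). Outside the list, the largest falls included Adamts16 at -7.91 ± 0.53, Npnt at -5.16 ± 0.29 and Gpr165 at -4.74 ± 0.22 (edgeR adjusted p = 2.16e-11, 3.03e-13 and 2.84e-14). Cx3cr1, the fractalkine receptor gene, at -1.57 ± 0.29 and Tmem119 at -1.85 ± 0.24, named after their values were seen, fell too (edgeR adjusted p = 0.000140 and 1.57e-06). Of 25 measured cytokines and chemokines, 20 rose and 2 fell (20 and 2 adjusted over the list alone), with a median of 2.71 (camera adjusted p = 3.30e-13). Ccl5 rose by 7.22 ± 0.47 and Il1rn, the interleukin 1 receptor antagonist gene, by 6.73 ± 0.58 (edgeR adjusted p = 8.65e-10 and 4.40e-08). Il12b, with 2 counts in the saline group, had a mean of 0.0244 CPM there and 7.24 ± 4.09 after LPS. Tnf rose from 35.8 ± 14.4 to 484 ± 157 CPM and Il1b from 16.5 ± 6.93 to 238 ± 103 CPM, both named after their values were seen (edgeR adjusted p = 5.87e-10 and 2.17e-06). Of 29 measured interferon-stimulated genes, 28 rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 2.63 (camera adjusted p = 2.77e-27). The nucleic acid sensor gene Zbp1 rose by 5.28 ± 0.39, Ifi204 by 5.15 ± 0.23 and Ifitm3 by 4.88 ± 0.30 (edgeR adjusted p = 7.14e-10, 4.21e-14 and 9.48e-12). With an estimated in place of a preset correlation between members, the camera calls of these 3 lists held (adjusted p = 0.0104 homeostatic, 0.0313 cytokines and 0.0104 interferon-stimulated) and the others of this comparison did not.

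Innate sensing genes rose alongside. Of 26 measured TLR and NF-kB signalling genes, 19 rose and 2 fell (19 and 2 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 7.70e-08, adjusted p = 0.142 with an estimated correlation). Traf1 rose by 3.54 ± 0.38, Irak3, a negative regulator of the pathway, by 3.27 ± 0.25 and Tlr2, a receptor for bacterial lipoproteins, by 3.24 ± 0.26. In antigen presentation, 11 of 19 genes rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.000134, adjusted p = 0.240 with an estimated correlation), and Nlrc5, a transactivator of MHC class I genes, rose by 3.51 ± 0.16, Cd74 by 2.55 ± 0.22 and the peptide transporter gene Tap1 by 2.00 ± 0.17. The disease-associated microglia and lysosome list split, with 9 of 21 genes higher and 5 lower (9 and 5 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.0119, adjusted p = 0.293 with an estimated correlation). Its Spp1, encoding osteopontin, rose by 7.22 ± 0.52 and Lgals3, encoding galectin 3, by 4.19 ± 0.52. Among 12 complement genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 0.00193, adjusted p = 0.245 with an estimated correlation), led by C3 at 7.21 ± 0.69, Cfb at 5.11 ± 0.74 and C4b at 4.50 ± 0.45. Of 18 phagocytic receptors and bridging factors, 9 rose and 4 fell (9 and 5 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 0.00467, adjusted p = 0.240 with an estimated correlation). The scavenger receptor gene Msr1 rose by 8.27 ± 0.34 and the Fc receptor gene Fcgr4 by 5.40 ± 0.23. Other large rises were Trem1 at 10.58 ± 0.58, Acod1, which makes itaconate, at 9.34 ± 0.71 and the acute phase gene Saa3 at 8.84 ± 0.90. The edgeR adjusted p of the genes named in this paragraph ran from 5.86e-15 for Nlrc5 to 3.45e-06 for Cfb.

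Many metabolic and translation genes rose. Of 18 glycolysis genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 0.000609, adjusted p = 0.253 with an estimated correlation), and Pfkfb3, a regulator of glycolytic flux, rose by 3.32 ± 0.15, Gpi1 by 1.51 ± 0.17 and Pkm by 1.42 ± 0.14. Oxidative phosphorylation had 21 of 27 genes higher and 0 lower (21 and 0 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 0.000113, adjusted p = 0.253 with an estimated correlation), among them the cytochrome c gene Cycs at 1.19 ± 0.19 and Cyc1 at 1.06 ± 0.17. Ribosomal protein genes rose in 18 of 24 cases and fell in 0 (18 and 0 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 4.26e-05, adjusted p = 0.330 with an estimated correlation), with Rps2 at 1.37 ± 0.16 and Rps18 at 1.17 ± 0.15. Of 14 glucocorticoid-responsive genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 0.00223, adjusted p = 0.209 with an estimated correlation). Its largest rises were the metallothionein gene Mt2 at 6.54 ± 0.62, Zbtb16 at 4.42 ± 0.59 and Klf9 at 4.12 ± 0.31. No direction was called by camera for 3 lists. Cell cycle genes rose in 4 of 18 cases and fell in 2 (4 and 1 adjusted over the list alone, camera adjusted p = 0.378, adjusted p = 0.438 with an estimated correlation), where the replication helicase gene Mcm6 rose by 1.41 ± 0.19, the mitotic checkpoint gene Bub1b rose by 1.92 ± 0.50 and the proliferation marker Mki67 fell (-1.20 ± 0.28). Immediate early and dissociation stress genes rose in 4 of 23 cases and fell in 10 (4 and 11 adjusted over the list alone, camera adjusted p = 0.0677, adjusted p = 0.561 with an estimated correlation), with Fosb at -2.34 ± 0.30, Dnajb1 at -1.70 ± 0.37 and Ier3 at 2.15 ± 0.25. Chromatin modifiers rose in 5 of 25 cases and fell in 7 (5 and 7 adjusted over the list alone, camera adjusted p = 0.516, adjusted p = 0.515 with an estimated correlation). The deacetylase gene Hdac4 rose by 1.75 ± 0.21, while Hdac5 stood at -1.46 ± 0.17 and the DNA methyltransferase gene Dnmt3a at -1.18 ± 0.12. The edgeR adjusted p of the genes named in this paragraph was at most 0.00280 (Bub1b). For every gene named as risen or fallen in control offspring so far, all 5 LPS libraries lay beyond all 6 saline libraries, except Mki67 with 3 of 5. By chance 2 of 462 divisions of 11 libraries part them so, a share that does not apply as a test to genes named for their change between the same libraries.

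**Figure D3:**
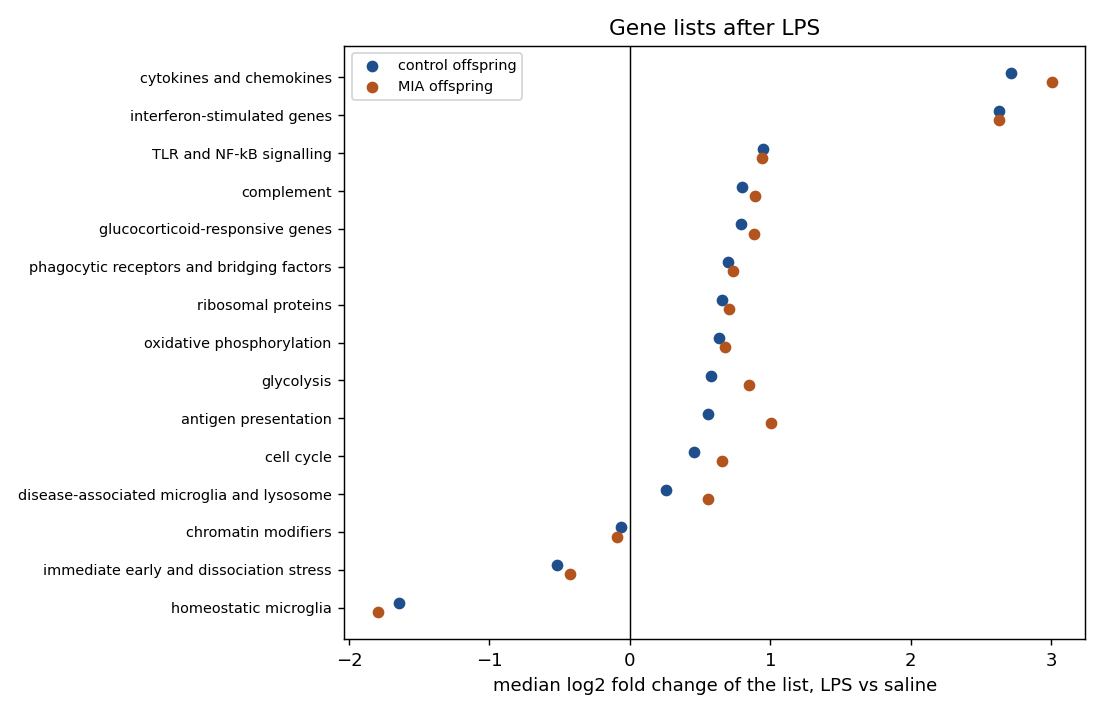
Median log2 fold change, LPS against saline, of the 15 gene lists, with blue points for control and orange points for MIA offspring. The homeostatic list lies at -1.64 and -1.79, cytokines at 2.71 and 3.00, and interferon-stimulated genes at 2.63 and 2.63.

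Markers of blood leukocytes moved with the gene groups that rose. Of 7 monocyte markers 6 rose and 1, Ccr2, fell (6 and 1 adjusted over the list alone, median 4.84, camera adjusted p = 0.00778, adjusted p = 0.0903 with an estimated correlation), and their summed CPM was 5.08 ± 0.894 after saline and 68.8 ± 15.2 after LPS. Of 10 neutrophil markers 7 rose and 1, Csf3r, fell (7 and 1 adjusted over the list alone, median 3.90, camera adjusted p = 0.0409, adjusted p = 0.522 with an estimated correlation). Their summed CPM, most of it Csf3r after saline, was 191 ± 19.4 after saline and 156 ± 24.3 after LPS. S100a8 went from 1.47 ± 1.96 to 20.3 ± 5.68 CPM and S100a9 from 2.04 ± 3.06 to 34.2 ± 10.6 CPM, while Csf3r went from 180.2 ± 22.1 to 71.0 ± 19.7 CPM. The border-associated macrophage list had 1 member higher (F13a1) and 1 lower (Mrc1) of 7 (0 and 1 adjusted over the list alone, camera adjusted p = 0.471). Astrocyte markers had 1 higher (Gfap) and 1 lower (Slc1a3) of 6 (1 and 1 adjusted over the list alone, camera adjusted p = 0.838). Endothelial and mural markers had 1 of 4 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.701), and erythroid and choroid plexus markers 2 of 3 lower, Hbb-bs and Hbb-bt (0 and 2 adjusted over the list alone, camera adjusted p = 0.701). The summed CPM of this last list was 34.7, 21.2 and 14.0 in control saline replicates 1, 3 and 4. It was 0.105 to 0.476 in the other control saline libraries and 0.205 to 5.09 after LPS. None of 8 neuron and 7 oligodendrocyte markers was called (camera adjusted p = 0.701 and 0.999, 0 members adjusted over the list alone). The lymphocyte list had 1 measured gene, not called over all genes (0 and 1 adjusted over the list alone), and no list test. The members named here were chosen after their values were seen. Leaving out any single library left 5927 to 7076 called genes.

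In MIA offspring (5 saline and 3 LPS libraries) the same comparison asked how the response ran after prenatal immune stress. Homeostatic genes fell and cytokine and interferon-response genes rose here too. P2ry12 fell from 2049.9 ± 223 CPM (SD, n = 5) to 203 ± 75.4 (SD, n = 3), a log2 fold change of -3.33 ± 0.21 (SE). Lcn2 had 0 counts in the 5 saline libraries and 261 ± 191 CPM after LPS, at least 5924-fold higher, and Marco 0 counts and 31.9 ± 26.4 CPM, at least 725-fold higher. With the replicate number of the titles as a block, Marco was not called (edgeR adjusted p = 0.0615), at a fitted log2 fold change of 11.5. Ccl5 rose from 0.684 ± 0.633 to 134 ± 41.3 CPM. The edgeR quasi-likelihood test called 5765 genes, 3064 higher and 2701 lower, at a Benjamini-Hochberg adjusted p under 0.05, and 1597 higher and 1587 lower genes changed at least 2-fold. Which direction held more genes depended on the scaling, with 2734 and 2997 higher and lower under RLE, 2636 and 3094 under upper quartile scaling and 2814 and 3191 by DESeq2.

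Of the 26 homeostatic genes 23 fell and 1 rose (1 and 23 adjusted over the list alone), with a median log2 fold change of -1.79 (camera adjusted p = 1.24e-21, adjusted p = 0.00767 with an estimated correlation). Slc2a5 changed by -5.35 ± 0.28 (log2 fold change ± SE), Gpr34 by -4.90 ± 0.37 and Crybb1 by -3.45 ± 0.34 (edgeR adjusted p = 1.90e-13, 5.92e-10 and 5.99e-08). Cx3cr1 at -2.10 ± 0.37 and Tmem119 at -1.92 ± 0.30, named after their values were seen, fell (edgeR adjusted p = 0.000102 and 2.33e-05), as did Adamts16 at -6.40 ± 0.56, Npnt at -5.15 ± 0.35 and Gpr165 at -4.90 ± 0.29 (edgeR adjusted p = 3.32e-09, 2.81e-11 and 3.01e-12). Among 25 cytokines and chemokines 21 rose and 2 fell (22 and 2 adjusted over the list alone), with a median of 3.00 (camera adjusted p = 4.17e-14, adjusted p = 0.0282 with an estimated correlation). Il1rn rose by 7.61 ± 0.67 and Ccl5 by 7.67 ± 0.55 (edgeR adjusted p = 9.28e-08 and 5.71e-09), and Il12b, at 0 counts after saline, was at least 92.2-fold higher. Tnf went from 37.4 ± 9.90 to 614 ± 189 CPM and Il1b from 14.3 ± 2.78 to 265 ± 169 CPM (edgeR adjusted p = 2.74e-09 and 5.60e-06), both named after their values were seen. All 29 measured interferon-stimulated genes rose (29 and 0 adjusted over the list alone), with a median of 2.63 (camera adjusted p = 1.58e-26, adjusted p = 0.00767 with an estimated correlation). Ifi204 rose by 5.11 ± 0.27, Zbp1 by 5.03 ± 0.44 and the interferon-induced GTPase gene Gbp2 by 4.79 ± 0.29 (edgeR adjusted p = 7.95e-13, 1.49e-08 and 5.93e-12). These 3 lists were the ones whose camera calls held with an estimated correlation.

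TLR and NF-kB signalling genes rose in 18 of 26 cases and fell in 2 (18 and 2 adjusted over the list alone, median 0.94, camera adjusted p = 2.26e-07, adjusted p = 0.114 with an estimated correlation), with Traf1 at 3.35 ± 0.44, Irak3 at 3.17 ± 0.29 and Tlr2 at 3.05 ± 0.30. Antigen presentation had 13 of 19 genes higher and 1 lower (13 and 1 adjusted over the list alone, median 1.00, camera adjusted p = 3.44e-05, adjusted p = 0.212 with an estimated correlation), and Nlrc5 rose by 3.39 ± 0.19 and Cd74 by 3.11 ± 0.26. In the disease-associated microglia and lysosome list 10 of 21 genes rose and 4 fell (10 and 5 adjusted over the list alone, median 0.56, camera adjusted p = 0.00419, adjusted p = 0.228 with an estimated correlation), with Spp1 at 8.04 ± 0.61 and Lgals3 at 4.41 ± 0.63. Complement had 7 of 12 genes higher and 1 lower (9 and 1 adjusted over the list alone, median 0.89, camera adjusted p = 0.00458, adjusted p = 0.228 with an estimated correlation), with C3 at 5.28 ± 0.66 and C4b at 4.83 ± 0.53. Phagocytic receptors and bridging factors rose in 8 of 18 cases and fell in 5 (9 and 5 adjusted over the list alone, median 0.73, camera adjusted p = 0.00454, adjusted p = 0.227 with an estimated correlation), with Msr1 at 8.13 ± 0.38 and Fcgr4 at 5.10 ± 0.26. Glycolysis genes rose in 11 of 18 cases and fell in 1 (11 and 1 adjusted over the list alone, median 0.85, camera adjusted p = 5.05e-05, adjusted p = 0.212 with an estimated correlation), Pfkfb3 by 3.50 ± 0.17 and Gpi1 by 1.59 ± 0.19. Oxidative phosphorylation genes rose in 21 of 27 cases and fell in 0 (22 and 0 adjusted over the list alone, median 0.68, camera adjusted p = 0.000110, adjusted p = 0.228 with an estimated correlation), Cox5a by 0.94 ± 0.19. Ribosomal protein genes rose in 15 of 24 cases and fell in 0 (16 and 0 adjusted over the list alone, median 0.71, camera adjusted p = 5.17e-05, adjusted p = 0.318 with an estimated correlation), Rps2 by 1.46 ± 0.18. Glucocorticoid-responsive genes rose in 8 of 14 cases and fell in 0 (9 and 0 adjusted over the list alone, median 0.89, camera adjusted p = 0.000359, adjusted p = 0.114 with an estimated correlation), Mt2 by 8.08 ± 0.73, Zbtb16 by 6.52 ± 0.76 and Klf9 by 4.29 ± 0.36. No direction was called for cell cycle genes, 5 of 18 higher and 1 lower (5 and 1 adjusted over the list alone, median 0.65, camera adjusted p = 0.124, adjusted p = 0.227 with an estimated correlation), immediate early and dissociation stress genes, 3 of 23 higher and 7 lower (4 and 9 adjusted over the list alone, median -0.43, camera adjusted p = 0.139, adjusted p = 0.644 with an estimated correlation), or chromatin modifiers, 4 of 25 higher and 6 lower (4 and 6 adjusted over the list alone, median -0.09, camera adjusted p = 0.536, adjusted p = 0.537 with an estimated correlation). Mki67 (-1.15 ± 0.34), Fosb (-2.36 ± 0.37), Hdac5 (-1.51 ± 0.21) and Dnmt3a (-1.40 ± 0.15) fell and Bub1b (2.03 ± 0.58), Ier3 (1.98 ± 0.29) and Hdac4 (2.15 ± 0.24) rose. The edgeR adjusted p of the genes named in this paragraph was at most 0.00884. For every gene named as risen or fallen in MIA offspring so far, all 3 LPS libraries lay beyond all 5 saline libraries. By chance 2 of 56 divisions of 8 libraries part them so, a share that does not apply as a test to genes named for their change between the same libraries. Without the batch term, which lets the batch 2 library count, Bub1b and Hdac5 were no longer called, at 1.64 and -0.27.

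Leukocyte markers moved with these groups in MIA offspring as well. Monocyte markers rose in 6 of 7 cases and Ccr2 fell (6 and 1 adjusted over the list alone, median 5.37 with genes at 0 set to their bound, camera adjusted p = 0.0102, adjusted p = 0.0687 with an estimated correlation), and their summed CPM was 4.79 ± 1.42 after saline and 48.9 ± 9.67 after LPS. Neutrophil markers rose in 9 of 10 cases and Csf3r fell (9 and 1 adjusted over the list alone, median 5.82 with genes at 0 set to their bound, camera adjusted p = 0.0102, adjusted p = 0.348 with an estimated correlation). Their summed CPM was 191 ± 15.3 after saline and 128 ± 50.1 after LPS. S100a9 had 0 counts after saline and 33.6 ± 20.1 CPM after LPS, at least 763-fold higher. The border-associated macrophage list had 1 of 7 higher (F13a1) and 2 lower, Mrc1 and Lyve1 (1 and 2 adjusted over the list alone, camera adjusted p = 0.901), and the astrocyte list 1 of 6 higher (Gfap) and 1 lower, Slc1a3 (1 and 1 adjusted over the list alone). Of 4 endothelial and mural markers 1 was lower (0 and 1 adjusted over the list alone), and none of the measured neuron, oligodendrocyte, lymphocyte and erythroid markers was called, over all genes or adjusted over the list alone. Camera adjusted p was 0.901 for each of the neuron, astrocyte, oligodendrocyte, endothelial and erythroid lists. The batch 2 library, MIA LPS replicate 4, had no weight in this contrast and held 96.5 CPM of P2ry12, 709 of Lcn2, 1228 of Marco, 1562 of Ccl5 and 28.2 of Il1b. Leaving out any single library left 4814 to 5879 called genes.

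Responses of the 2 maternal groups shared 2667 genes called higher and 2263 called lower, against 714.8 and 575.5 if the calls were independent, and 0 genes were called in opposite directions. Across the 14741 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.899 and a Spearman rho of 0.863. No library served in both fold changes. Genes with the largest changes lay apart in GRCm38 coordinates of the GENCODE M21 annotation. Marco lay on chromosome 1, 120474538 to 120505024, Il1r2 on chromosome 1, 40074079 to 40125231, Lcn2 on chromosome 2, 32384633 to 32388252, Slc2a5 on chromosome 4, 150119283 to 150144169, Adamts16 on chromosome 13, 70727802 to 70841811 and P2ry12 on chromosome 3, 59216272 to 59262871. Counts were per gene, so no exon or untranslated region is distinguished. Values of genes with close copies in the genome, such as Saa3, Gbp2, Ifi204, Ms4a7, H2-Aa, Hbb-bs and Hbb-bt, are uncertain, since reads shared between copies are divided by estimate.

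The title of the series links prenatal immune stress to blunted reactivity of microglia, a question that the difference of the LPS responses, MIA minus control, addresses. The edgeR quasi-likelihood test called 0 of 14741 genes, with 491 at an unadjusted p under 0.05 (3.33%), and limma-voom with sample weights and DESeq2 called 0 each. The response of P2ry12 differed by 0.06 ± 0.24 (log2 ± SE), that of the sort markers Itgam and Ptprc by -0.03 ± 0.23 and 0.06 ± 0.22, and those of Tnf and Il1b, named after their values were seen, by 0.28 ± 0.40 and 0.36 ± 0.65 (edgeR adjusted p = 1.00 for each of these genes). Over the 8187 genes with a called mean LPS effect of both maternal groups, the response in MIA offspring was larger by a median of 0.0637 on the log2 scale, and 41.1% of them had a smaller response in MIA. Of 100 splits of these libraries between the maternal groups, 23 gave a median at least as far from 0, so chance cannot be excluded for this direction. At 3524 genes whose mean effect was at least 2-fold, the median was 0.0915. Over the 8187 genes, the orthogonal slope through 0 of the MIA against the control response was 1.057. This slope weighs deviations of both responses alike, and no chance range was computed for it.

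The lowest unadjusted p values belonged to genes that did not pass: Platr25 at -1.04 ± 0.24, Nipal3 at -1.21 ± 0.30, Synj2bp at -0.77 ± 0.19, Rab39 at -0.79 ± 0.20 and Tef at 1.30 ± 0.34 (edgeR adjusted p = 1.00 for each). Crybb1, whose fall was smaller in MIA offspring, differed by 1.20 ± 0.41 (edgeR adjusted p = 1.00). No biology list was called by camera (lowest adjusted p = 0.112, shared by glycolysis, cell cycle and glucocorticoid-responsive genes), and 0 members passed when adjusted over the list alone. Camera called 3 lists without MIA LPS replicate 2, 2 without MIA LPS replicate 1, and 1 without control LPS replicate 1 or 3, MIA saline replicate 2 or control saline replicate 6. It called 2 without the batch term. List medians were 0.02 for homeostatic, 0.28 for cytokine, 0.01 for interferon-stimulated, 0.01 for TLR and NF-kB and 0.06 for antigen presentation genes. Those of interferon-stimulated and of TLR and NF-kB genes turned negative under other scalings. Among cell type lists the neutrophil list was higher (camera adjusted p = 0.0251, adjusted p = 0.713 with an estimated correlation). The median MIA minus control difference of this list was -2.17 after saline, with genes at 0 set to their bound, and 0.01 after LPS. In simulated counts with the real libraries' depth and spread, this test recovered 44% of 2-fold and 84% of 4-fold differences at genes above a minimum mean expression. Genes were drawn independently there, so structure shared by the real libraries was not covered. A simulated response of 75% in MIA offspring gave a median of -0.24 and 25 called genes, and one of 100% gave 0.0174 and 0. Without MIA LPS replicate 1 the test called 2 genes, Gm15801 and Lpar5, and without control saline replicate 4 it called 1, Gm12191, all lower in MIA and named only for those calls. The median was 0.116 without MIA LPS replicate 1, 0.117 without MIA LPS replicate 2 and 0.175 without the batch term, which lets the batch 2 library count.

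**Figure D4:**
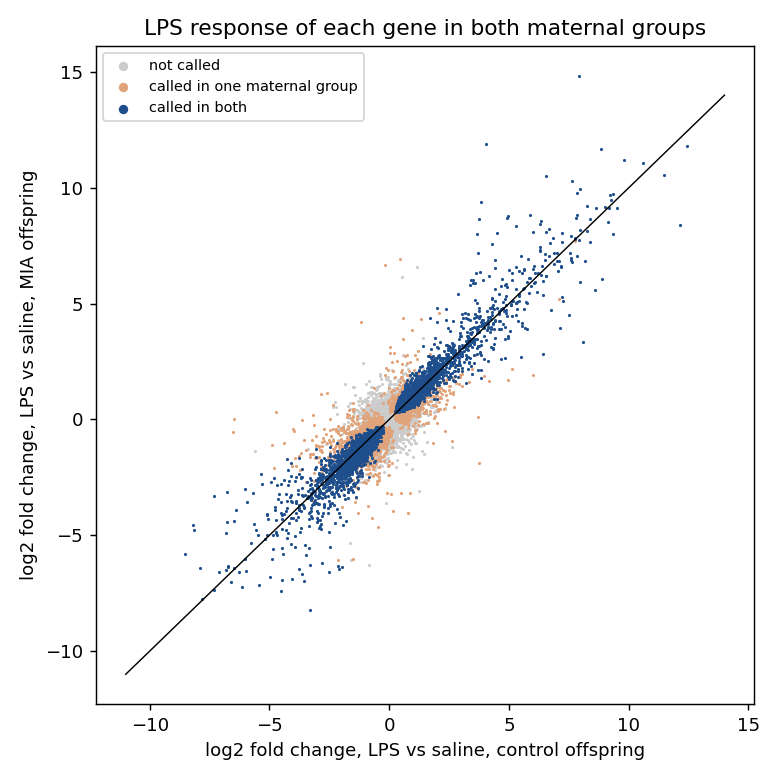
Log2 fold change of LPS against saline for 14741 genes, control offspring on the horizontal and MIA offspring on the vertical axis, with colours for genes called in both, in 1 or in no maternal group and a line of equal response. The 2667 genes called higher and 2263 called lower in both groups lie along the line, with a Pearson r of 0.899 across all genes.

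Between MIA and control offspring after saline (5 and 6 libraries), the question was whether resting microglia differed. The edgeR quasi-likelihood test called 0 of 14741 genes (lowest adjusted p = 0.698, 415 genes or 2.82% at an unadjusted p under 0.05), limma-voom with sample weights 0 and DESeq2 6. P2ry12 stood at 1974 ± 198 CPM in control and 2049.9 ± 223 in MIA offspring (0.05 ± 0.15, log2 ± SE), and Itgam and Ptprc differed by 0.12 ± 0.14 and 0.06 ± 0.14. With no member called, the border-associated macrophage list was lower in MIA offspring (camera adjusted p = 1.38e-08, adjusted p = 0.0370 with an estimated correlation). Its Cd163 had 0.683 ± 0.528 CPM against 2.07 ± 0.523 and Pf4 1.14 ± 0.903 against 3.07 ± 1.80 (SD, n = 5 and 6). The oligodendrocyte list was higher (camera adjusted p = 1.13e-06, adjusted p = 0.0370 with an estimated correlation). Lcn2 had 0 counts in the 5 MIA libraries and 1.14 ± 1.00 CPM in the 6 control libraries, all of which held it, while the MIA saline library titled excluded held 0.767 CPM. S100a9 had 0 counts in the 5 MIA libraries and 2.04 ± 3.06 CPM in the control libraries. The members named here, Lcn2 and S100a9 were chosen after their values were seen.

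The 6 genes called by DESeq2 were Igfbp6, Gm14303 and Gm37651, higher in MIA, and Lcn2, S100a9 and Gm45837, lower. Igfbp6, an insulin-like growth factor binding protein gene, had 0 counts in control saline libraries and 0.303 ± 0.270 CPM in MIA, at least 9.12-fold higher, with 4 of 5 MIA libraries above all controls (edgeR adjusted p = 0.698). For Lcn2 and S100a9 the edgeR adjusted p was 1.00 each. Other genes below the threshold were Hyls1 at -1.05 ± 0.27, Pcp4 at 1.21 ± 0.32 and the MHC class II gene H2-Aa at -3.22 ± 0.85 (edgeR adjusted p = 1.00 each). By camera, 4 biology lists were called: immediate early and dissociation stress genes higher (median 0.35, adjusted p = 1.67e-10), ribosomal protein genes higher (0.12, 0.000280), TLR and NF-kB genes higher (0.10, 0.0311) and cell cycle genes lower (-0.15, 0.0311). With an estimated correlation the adjusted p values were 0.381, 0.940, 0.940 and 0.276. The count of 4 lists was 1 without MIA saline replicate 2 and 2 without control saline replicate 6. Adjusted over the list alone, 1 cytokine gene was higher (Cxcl9), 1 antigen presentation gene lower (H2-Aa) and 0 members of the other biology lists differed.

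The border-associated macrophage list had a median of -1.40 and the oligodendrocyte list of 1.11, with 0 members called over all genes or adjusted over the list alone. By fry, which tests whether a list's genes move 1 way on balance, neither was called (adjusted p = 0.0982 for both). Adjusted over the list alone, 4 of 10 neutrophil markers were lower in MIA offspring, S100a8, S100a9, Ltf and Camp (median -2.17 with genes at 0 set to their bound, camera adjusted p = 0.000105, adjusted p = 0.0714 with an estimated correlation), and 2 of 3 erythroid markers, Hbb-bs and Hbb-bt (median -3.63, camera adjusted p = 0.0118, adjusted p = 0.194 with an estimated correlation). The erythroid sum was 34.7, 21.2 and 14.0 CPM in control saline replicates 1, 3 and 4. It was 0.105 to 0.476 CPM in the other controls and 0.197 to 4.39 in the MIA libraries. Neuron, astrocyte, monocyte and endothelial lists were not called (camera adjusted p = 0.0707, 0.136, 0.238 and 0.835). With an estimated correlation the border macrophage call was lost without any 1 of MIA saline replicates 1, 2 and 3, control saline replicates 3 and 5 and MIA LPS replicates 1 and 2 (adjusted p = 0.0504 to 0.108). The oligodendrocyte call was lost without any 1 of MIA saline replicates 1 to 4, control saline replicate 5 and MIA LPS replicate 2 (adjusted p = 0.0592 to 0.101). In simulated counts with independent genes, 2-fold and 4-fold differences between these groups were recovered for 79% and 97% of changed genes, all above a minimum mean expression.

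**Figure D5:**
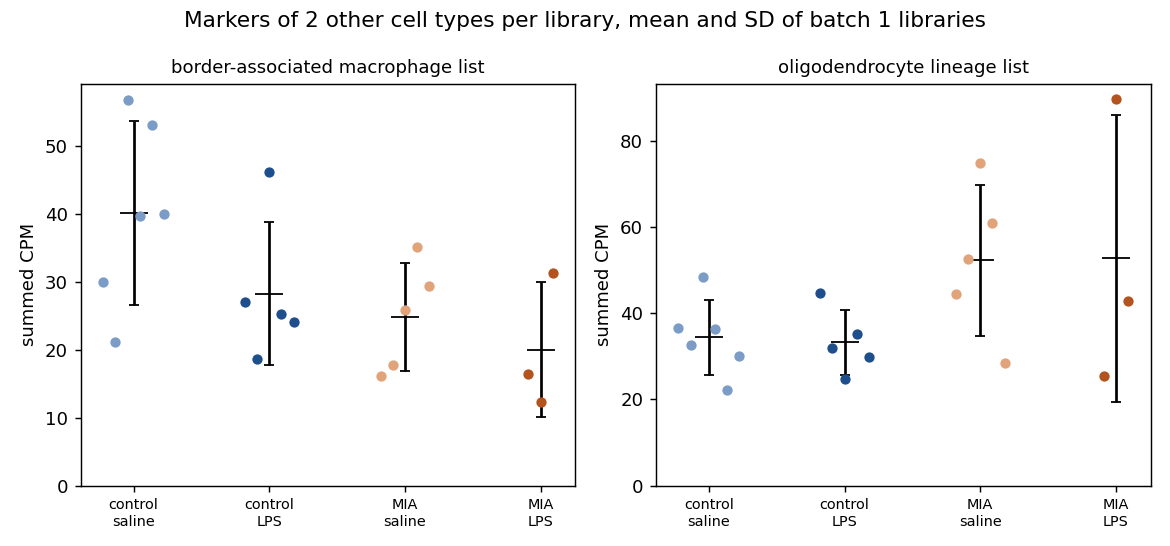
Summed CPM of the border-associated macrophage list and of the oligodendrocyte list on linear axes, with a point for each batch 1 library and bars for mean and SD of each group. After saline the sums were 40.1 ± 13.5 in control and 24.8 ± 7.95 in MIA offspring for the first list and 34.4 ± 8.67 and 52.3 ± 17.4 for the second.

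Between MIA and control offspring after LPS (3 and 5 libraries), the question was whether challenged microglia differed. The edgeR quasi-likelihood test called 0 of 14741 genes (lowest adjusted p = 0.617, 825 genes or 5.60% at an unadjusted p under 0.05), and limma-voom with sample weights and DESeq2 called 0 each. P2ry12 held 188 ± 17.3 CPM in control and 203 ± 75.4 in MIA offspring (0.11 ± 0.18, log2 ± SE), Lcn2 282 ± 112 and 261 ± 191 and Tnf 484 ± 157 and 614 ± 189 (SD, n = 5 and 3). Lcn2 and Tnf were named after their values were seen. Itgam and Ptprc differed by 0.10 ± 0.17 and 0.12 ± 0.17. Genes with the lowest p, below the threshold, were Platr25 at -0.89 ± 0.19, Nipal3 at -1.06 ± 0.24, the small heat shock protein gene Hspb1 at 2.17 ± 0.52 and the clock output transcription factor gene Tef at 1.06 ± 0.27 (edgeR adjusted p = 0.617 each). Camera called immediate early and dissociation stress genes higher (median 0.36, adjusted p = 9.24e-08), ribosomal protein genes higher (0.14, 0.0111) and glycolysis genes higher (0.15, 0.0249), each at an adjusted p = 0.835 with an estimated correlation. The count of these 3 lists was 7 without MIA LPS replicate 2 and 1 without MIA LPS replicate 3. Adjusted over the list alone, 1 TLR and NF-kB gene was higher (Zc3h12a), 1 lower (Tlr4) and 0 members of the other biology lists differed. Among cell type lists, astrocyte markers were higher in MIA offspring (3 of 6 adjusted over the list alone, Slc1a2, Aldoc and Gja1, camera adjusted p = 0.0150, adjusted p = 0.328 with an estimated correlation), as were oligodendrocyte markers (camera adjusted p = 0.00570, adjusted p = 0.328 with an estimated correlation). Summed astrocyte CPM was 235 in MIA LPS replicate 2 and 118 and 119.7 in the other 2. Summed oligodendrocyte CPM was 89.7 in MIA LPS replicate 2 and 25.5 and 42.9 in the other 2, against 24.7 to 44.8 in the control LPS libraries. Border macrophage, monocyte, neutrophil, neuron, endothelial and erythroid lists were not called (camera adjusted p = 0.162, 0.162, 0.601, 0.364, 0.380 and 0.837). In simulated counts with independent genes this test recovered 65% of 2-fold and 95% of 4-fold differences at genes above a minimum mean expression. Without MIA LPS replicate 1 it called 4 genes lower in MIA (Gm15801, Lpar5, Slc38a9 and Card6) and without MIA LPS replicate 3 it called 3 higher (Rhobtb1, Gas2l3 and Tef), all but Tef named only for those calls.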

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

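Of the tests in this part, those of carry-over and of depth for MIA LPS replicate 2, of ID number 3 for the oligodendrocyte list, of chance for the border macrophage list and of induction for the leukocyte markers were chosen only after the result was seen. MIA LPS replicate 2 stood apart from the other 7 LPS libraries of batch 1 on the second principal component, and had the highest mitochondrial share (7.30%, others 3.62 to 6.11%) and Malat1 share (0.796%, others 0.505 to 0.740%) of these 8, so that RNA quality stays open, as untested. Low depth is argued against, since its total of 13.3 M lay above the 9.85 M of another LPS library. Carry-over of other brain cells cannot be told apart from other sources: its astrocyte sum (235 CPM, at most 146 in the others) and oligodendrocyte sum were the highest of the LPS libraries. Its homeostatic sum of 21199 CPM lay within the 16843 to 21391 of the others, and the CD11b and P2RY12 gates should remove such cells. That sum rests much on Cst3, which took 1.48% of all counts on average, and does not stand for every member. Cx3cr1, at 234 CPM, lay below the 849 to 1869 of the others, and P2ry12, at 269 CPM, above their 121 to 220. A weaker LPS response in this mouse cannot be told apart either, with a slope of 0.893 on the mean control response against 0.954 to 1.06 in the other LPS libraries.

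After saline, border macrophage markers were lower and oligodendrocyte markers higher in MIA than in control offspring, and no member of either list stood in another list. Different carry-over of other cells between libraries is a candidate source, though the CD45-low and P2RY12 gates should remove these cells. Within saline groups the 7 border macrophage markers moved together (median pairwise r = 0.730, percentile 100 of 1000 expression-matched random lists). Genes regulated together could give such an r as well, so it does not favour carry-over. It was taken on deviations from group means, so it does not measure the MIA against control difference. Of the more abundant genes of the lists, Mrc1 (22.2 CPM in control, 17.5 in MIA) and Mbp (14.2 and 14.6) stood closer between the groups than the list medians. Named after their values were seen, they were the members of their lists that differed least (log2 -0.337 and 0.0399). All 7 measured members of each list differed in the direction of the list. Chance stays open too, as the exact permutation p over 462 splits was 0.165 for the border macrophage list after adjustment over 8 cell type lists (unadjusted 0.0411, two-sided). That the 2 MIA libraries of ID number 3 alone made the difference is argued against for the oligodendrocyte list, whose median was 1.23 without them and 1.11 with them (standard error 0.46, adjusted p = 0.110 with an estimated correlation). For the border macrophage list it cannot be told apart, since its median was -0.89 without them and -1.40 with them (standard error 0.44, adjusted p = 0.245), and a difference brought by MIA itself stays open, as untested.

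Most measured neutrophil and monocyte markers were higher after LPS in both maternal groups, while Ccr2 and Csf3r were lower in both. Summed neutrophil CPM went from 191 to 156 in control and from 191 to 128 in MIA offspring. Carry-over of blood leukocytes is a candidate source, although CD45-high leukocytes lie outside the gate. Within LPS groups the 15 risen markers had a median pairwise r of 0.271 (percentile 99.8 of random lists, whose 95th percentile was 0.125). It was 0.313 within neutrophil markers and 0.0609, below that cut, within monocyte markers. The random lists were matched on expression and not on the response to LPS. Genes raised together by LPS could give such an r as well, so it does not favour carry-over. Of the abundant neutrophil genes, S100a9 reached 34.2 ± 10.6 CPM in control offspring after LPS and S100a8 20.3 ± 5.68 CPM, while Csf3r stood at 180.2 CPM after saline already and which cells it came from was not tested. Induction along with each library's overall response cannot be told apart, as the within-group r of marker mean and first principal component was -0.0180 with a standard error of 0.500 over 8 libraries (exact permutation p = 0.956, Spearman rho -0.119 with exact permutation p = 0.819, r -0.229 without the 2 farthest libraries).

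Among 229 checks for a sample far from the others of its group, 17 found one. Chance gives about 1 in 20 (11.45) if values spread normally. That share does not apply where all other libraries of the group held 0, as for Trem1, Cfb and, in MIA saline, Acod1. On the first principal component MIA saline replicate 3 lay at -63.5, against -58.0 to -56.3 in the other MIA saline libraries. Control saline replicate 5 stood apart for 3 genes, with Ptprc at 238 CPM against 289 to 318 in the other libraries of the group, Zbp1 at 2.68 CPM against 0.339 to 0.735 and Cd74 at 37.9 CPM against 14.4 to 19.9. Other control saline libraries stood apart for Trem1 (replicate 1, 0.282 CPM against 0), C3 (replicate 1, 0.395 CPM against 0 to 0.0768), Il1b (replicate 2, 4.95 CPM against 14.0 to 25.5), Acod1 (replicate 3, 0.695 CPM against 0 to 0.117) and Fosb (replicate 6, 143 CPM against 216 to 269). Control LPS libraries did so for Fosb (replicate 1, 89.9 CPM against 30.5 to 35.4) and Adamts16 (replicate 3, 0.311 CPM against 0 to 0.0542). MIA saline libraries did so for Acod1 (replicate 1, 0.614 CPM against 0), Mt2 (replicate 1, 0.175 CPM against 0.600 to 0.826), Tap1 (replicate 2, 7.79 CPM against 10.6 to 11.8), Mki67 (replicate 2, 3.37 CPM against 4.93 to 5.70), Cfb (replicate 3, 0.203 CPM against 0) and Cox5a (replicate 4, 22.7 CPM against 16.4 to 17.1). Among libraries without weight in the comparisons, the batch 2 library held a summed monocyte marker level of 95.9 CPM and a neutrophil marker level of 329.7 CPM, above the control saline libraries at 4.01 to 6.06 and 164 to 211 CPM and above the LPS libraries of batch 1 at 37.8 to 79.6 and 88.9 to 184 CPM. The MIA saline library titled excluded held 7.00 CPM of the monocyte markers.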

How the results depend on the processing

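Fits without the ribosomal RNA gene, and counts of called lists under other settings, were chosen only after the result was seen. Called genes of LPS against saline in control (6580) and MIA offspring (5765) stayed within 1.5 times except at a mean CPM of at least 10 (3913 and 3595, with fewer genes tested) and at a 2-fold minimum (3232 and 3184). In the 13 other fits compared gene by gene, which exclude those without single libraries, 0 genes called in both changed direction. Leaving out single libraries gave 5927 to 7076 and 4814 to 5879 called genes. For the difference of responses, 0 genes became 1 with the ID number as a random block (Gm12191, named only for that call). It became 2 without MIA LPS replicate 1 and 1 without control saline replicate 4 (range 0 to 2). After saline, 0 became 6 by DESeq2, and leaving out libraries gave 0 throughout. After LPS, 0 became 4 without MIA LPS replicate 1 and 3 without MIA LPS replicate 3 (range 0 to 4). The size of the response, 0.0637, was positive in every fit, at 0.175 without the batch term and 0.0448 to 0.117 without single libraries (0.116 without MIA LPS replicate 1, 0.117 without replicate 2). The cause of these changes was not tested.

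With an estimated correlation, called biology lists went from 12 to 3 for LPS in either maternal group, from 4 to 0 after saline and from 3 to 0 after LPS, and fry called 0 in the last 2. For the difference of responses 0 called lists became 2 without the batch term, 3 without MIA LPS replicate 2, 2 without MIA LPS replicate 1 and 1 without control LPS replicates 1 or 3, MIA saline replicate 2 or control saline replicate 6 (range 0 to 3). After saline the count of 4 ran from 1 (without MIA saline replicate 2) to 6 (without MIA saline replicate 3), with 2 without control saline replicate 6. After LPS the count of 3 ran from 1 (without MIA LPS replicate 3) to 7 (without MIA LPS replicate 2). Leaving out libraries gave 12 to 13 called lists for LPS in either maternal group. With an estimated correlation the border macrophage and oligodendrocyte lists after saline were past the threshold in 18 and 20 of 28 fits (adjusted p = 0.00658 to 0.129 and 0.0109 to 0.129). Both were lost with the library titled excluded kept in (0.0595) and with the covariate (0.129), and the border macrophage list also with no filter (0.0694). The border macrophage call was lost without control saline replicate 3 (0.0807), control saline replicate 5 (0.101), MIA LPS replicate 1 (0.0504), MIA LPS replicate 2 (0.0592), MIA saline replicate 1 (0.108), MIA saline replicate 2 (0.0922) or MIA saline replicate 3 (0.0753). The oligodendrocyte call was lost without control saline replicate 5 (0.101), MIA LPS replicate 2 (0.0592), MIA saline replicate 1 (0.0807), MIA saline replicate 2 (0.0922), MIA saline replicate 3 (0.0753) or MIA saline replicate 4 (0.0873).

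Whether replicate numbers of the titles pair the libraries stays open, as no chance level was computed for the values given here. The 24 pairs with the same number had a median r of deviations of 0.0989 (-0.277 to 0.403, 12 over 0.1), and 8 of 19 libraries correlated best with their own number. Pairs with another number were less alike, with a median of -0.00977 (27 of 109 over 0.1). For the ID number, 10 pairs had a median of 0.0832 (5 over 0.1, 8 of 17 libraries best with their own), against -0.0347 (8 of 35 over 0.1) for other numbers of the same maternal group. With the replicate number of the titles as a replicate block, called genes were 6295, 5540, 0, 0 and 0, the size 0.0794, and called lists 1 for the difference of responses and 2 after saline.

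Values of named genes under other settings were compared with the reported fit. Of these, 1936 of 1938 (LPS in control) and 1931 of 1936 (LPS in MIA) kept their side of the threshold. So did 2193 of 2193 (difference), 322 of 323 (after saline) and 323 of 324 (after LPS). Direction was compared only where a gene was called in the reported fit or under the other setting, and 0 such values reversed. Values called in neither, among them all 2193 of the difference, were counted as kept whatever their sign. In MIA offspring Marco was lost under the replicate block, at a fitted log2 fold change of 11.5, and Bub1b and Hdac5 without the batch term. Ptprc was gained in both maternal groups, Igfbp6 after saline by DESeq2 and Tef after LPS. Other scalings moved the median of all genes by at most 0.0922 on the log2 scale. Depth limits genes under the filter, which were not tested. DESeq2 and the covariate were not run for the size of the response.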

Other observations

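The gene families in this part and the tests of other splits were chosen only after the result was seen. Families were taken by symbol, and the share of members called in the same direction in both maternal groups after LPS is given beside that of all 14741 genes. Of 24 families examined those named here are examples, and the 48 Fisher tests run on them are not reported, since families picked from the same data, with members that can move together, leave a test of independent members void. Of all genes, 18.1% were higher and 15.4% lower in both. Of proteasome subunit genes a larger share was higher (35 of 45 members, median log2 fold changes 0.72 in control and 0.87 in MIA offspring), 3 of which stand in the antigen presentation list. The share was also larger in translation initiation factors, Eif (30 of 55, medians 0.48 and 0.56), mitochondrial ribosomal proteins, Mrp (32 of 79, medians 0.49 and 0.51), DEAD-box helicases, Ddx (17 of 35, medians 0.43 and 0.66), RNA polymerase subunits, Polr (14 of 28, medians 0.50 and 0.59) and amino acid transporters, Slc7 (5 of 9, medians 1.23 and 1.32).

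Of immune families with close copies in the genome, whose single members are uncertain, these also had a larger share higher: guanylate-binding proteins, Gbp (7 of 8, medians 2.44 and 2.29), Ms4a (7 of 8, medians 4.49 and 4.77), schlafens, Slfn (7 of 8, medians 3.00 and 3.55) and Lilr and Pilr receptors (5 of 6, medians 4.02 and 4.01). Others had members in both directions, such as Cd300 (2 higher and 2 lower of 5, medians -0.89 and -0.82), Clec (4 and 1 of 11) and Cxcr with Ccr (4 and 5 of 12). Smad genes, which carry TGF-beta signals, were lower in both maternal groups in 5 of 7 cases (medians -0.45 and -0.42), and zinc finger genes named Zfp in 69 of 342 (medians -0.26 and -0.37), with 11 higher. Histone genes had 0 of 40 members higher and 9 lower (medians -0.76 and -0.78). They were taken by symbols that begin with Hist, or with H1 to H4 followed by a, b, c or f. The medians of the families named here kept their sign under RLE and upper quartile scaling.

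Other splits of the same libraries were counted for each comparison. For LPS in control offspring, 100 of 462 possible splits were run. Only the real one called as many as 6580 genes, and the highest other called 1245. For LPS in MIA offspring, only the real one of 56 splits called as many as 5765, and the highest other called 814. These shares are the lowest that the numbers of splits allow, so they argue against chance without excluding it. Where the real split called 0 genes, every split calls at least as many by construction, so these counts say nothing about chance: the difference of responses (100 of 100 splits, highest other 908), MIA against control after saline (100 of 100, highest other 31) and after LPS (56 of 56, highest other 555). Chance cannot be excluded for the size of the response (0.0637, 23 of 100 splits at least as far from 0, farthest other 0.125). Splits that call 908 or 555 genes, the highest for the difference of responses and for MIA against control after LPS, point to a structure of the samples whose source was not tested. The split with 555 grouped MIA LPS replicate 2 with control LPS replicates 2 and 5.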
